A study of Oncorhynchus mykiss with 18 samples.

How the data were processed

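Rainbow trout (Oncorhynchus mykiss) alevins, the fish between hatching and the end of the yolk sac, were kept at 14 °C in flowing water that carried 17α-ethinylestradiol (EE2), the synthetic estrogen of contraceptive pills. Per the labels, exposure ran for 96 hours from hatching, so that the fish were sampled whole at 4 days post-hatch. The groups were a solvent control with 0.01% dimethyl sulfoxide and EE2 at 5 measured concentrations: 1.13 and 1.57 ng/L at the low end, then 6.22, 16.3 and lastly 55.1 ng/L. RNA was taken from pools of 3 alevins, and each of the 6 groups held 3 pools (replicates A, B and C), which gave 18 libraries. Libraries were strand-specific and made from poly(A) RNA. A higher concentration that the series' design text names was not analysed here. Nothing in the labels says that the pools of a group came from separate tanks, so p-values measure the spread between these pools, which may be technical.

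Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38, quantified with kallisto and compared with DESeq2; the versions of the last 2 tools and the genome build were not stated in the sources used here. The deposited table of each library lists 79244 RefSeq transcripts with estimated counts, per the file headers. Per the same file headers, each deposited table also gives TPM (abundance scaled to length and to a common total), the transcript length and the effective length. The estimated counts were used, and the lengths served checks on length; TPM was not used. A deposited table that repeats the estimated counts of the series was not used. The authors' deposited DESeq2 tables, 1 per concentration, cover 28438 transcripts. Per the file headers, these deposited tables give the mean of normalised counts as their signal, the same in all tables. They also give, per the file headers, a deposited log2 fold change with its standard error. The last deposited value is an adjusted p-value (p_value), per the file headers. Values from the authors' tables are named as such wherever they are given.

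Transcripts were matched by accession without version to the RefSeq gene table of assembly GCF_013265735.2 (USDA_OmykA_1.1), which was used for names only. Of the 79244 transcripts 42410 (53.5%) matched, 1083 of them with the same version. Estimated counts of matched transcripts were summed by gene and rounded, and unmatched transcripts were kept as they were, which gave 61973 features: 25139 gene sums, of which 6932 have a symbol, and 36834 single transcripts. They are all called genes here. A single transcript or a near copy can gain or lose reads to a sister sequence, so that its change may not be that of a gene.

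Counts were filtered with filterByExpr, scaled with TMM factors and fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All 18 libraries entered 1 model with 12 residual degrees of freedom, and 46999 genes were tested. Each concentration was compared with solvent and 55.1 with 16.3 ng/L, and a trend was fitted on the log2 of the concentration plus 1. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with 0.05 as the threshold. Every p-value printed for a gene is such an adjusted value from edgeR unless another source is named, and errors of fold changes are standard errors. Levels are CPM, counts scaled to a common library total, as mean ± SD of 3 libraries. Where all libraries of a group were at 0 reads, the fold change was computed against a floor of 3 reads over the group. With 1 to 3 reads, a ratio is given with its 95% counting interval. Floors and ratios use summed reads over library totals without TMM factors, which the CPM levels carry, so they can differ from ratios of mean levels. Intervals and floors cover counting error only.

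Genes were grouped into 20 lists fixed before the data were examined, along with the comparisons, the rule for named genes and most of the alternatives. The reference table holds no product names, so members were found by symbol, or by synonym where a gene had no symbol, which made the lists shorter than planned and let in genes that match only by the shape of a symbol. Each list was compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2. Camera was run with its preset correlation of 0.01 and again with an estimated correlation. The p-values of the 20 lists were adjusted within each of 6 comparisons (120 tests, without 55.1 against 16.3 ng/L). Member counts are also given with p-values adjusted over the list alone.

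Named at 55.1 ng/L were the 10 genes with the largest rise and the 10 with the largest fall, among those past the threshold with a mean of at least 1 CPM and all 3 libraries on one side of the solvent mean. In every other comparison and the trend these were 5 and 5. All measured egg protein genes, the estrogen receptors and up to 4 changed members of every other list at 55.1 ng/L were also named. Added after their values were seen were picks of the same size among genes with a symbol, the genes npc1, npc2, gm2a, pla2g15 and apoe, the cartilage and bone list members, and members of lists named beside a small count.

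A benchmark concentration, the concentration at which a fitted curve leaves the solvent level by 1 residual SD, was computed for genes with a trend from 4 curve families (linear, power, Hill and exponential). Curves were fitted to log2 CPM by least squares over a grid of preset shapes, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The median, the 10th percentile and the 20th lowest value over genes are given with jackknife errors. On simulated curves, the estimate over the true value was 0.98 for linear, 1.15 for power, 1.18 for Hill and 1.01 for exponential curves, 1 shape of each; the last, added after seeing the data, is the family chosen for 256 of the 558 genes. On simulated counts made from these libraries, with 200 changed genes, between 39% and 49% of 2-fold changes and between 75% and 78% of 4-fold changes were found in the comparisons with solvent. In those comparisons 2 to 7 unchanged genes were called.

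Alternatives chosen at that time were DESeq2 size factors, no filter, a strict filter (1 CPM in 3 libraries), transcripts as listed, a fit to the 6 libraries of a comparison, a block for the replicate letter, DESeq2 1.42.0 (Wald test, local dispersion fit), a 2-fold minimum, other trend scales, the trend without the highest group, other benchmark settings, and leaving out each library. Added after seeing the data were libraries thinned to the lowest total, removal of each library's trend with transcript length, a trend within the 4 groups quantified in one way, a trend and a benchmark without the 1.13 and 1.57 ng/L groups, and lists without members matched by symbol shape. Plots were drawn with matplotlib 3.10.9.

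The deposited values show that the quantification differed between groups. Among transcripts longer than 2000 bases, the gap between length and effective length varied within each library in 12 libraries (the 1.13, 1.57, 6.22 and 16.3 ng/L groups) and was constant in the other 6 (solvent and 55.1 ng/L). Kallisto gives such a pattern when its sequence bias correction is on, although the notes do not say so. The comparison of 55.1 ng/L with solvent is therefore the only one with solvent within a single kind of quantification.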

Results

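Transcripts were counted by RNA sequencing in whole rainbow trout alevins at the end of the 96-hour exposure to EE2, with 3 pooled libraries in the solvent group and in each of 5 exposed groups. The series' title gives the purpose as a short embryo assay from which a transcriptomic benchmark dose of EE2 can be read. Library totals lay between 12658946 and 17076432 estimated counts in the solvent group and between 13013502 and 16122131 at 55.1 ng/L. They were higher at 1.13 ng/L (26160497 to 28166132) and 1.57 ng/L (23837786 to 32851570), lay between 15365201 and 16164585 at 6.22 ng/L, and between 19679734 and 29635724 at 16.3 ng/L. Pearson correlations of log2 CPM across genes lay between 0.882 and 0.918 within groups (genes are not independent replicates). The first principal component held 14.2% of the variance, and its scores ran from 70.7 to 103.5 for the libraries of 1.13 and 1.57 ng/L. Next came 16.3 ng/L (-10.4 to 11.9), then solvent (-41.8 to -15), 55.1 ng/L (-86.2 to -49.1) and 6.22 ng/L (-106.8 to -38.1). The 1.13, 1.57 and 16.3 ng/L groups also had the highest library totals and the largest median gaps between length and effective length. This component thus cannot be told apart from those traits of the libraries.

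**Figure D1:**
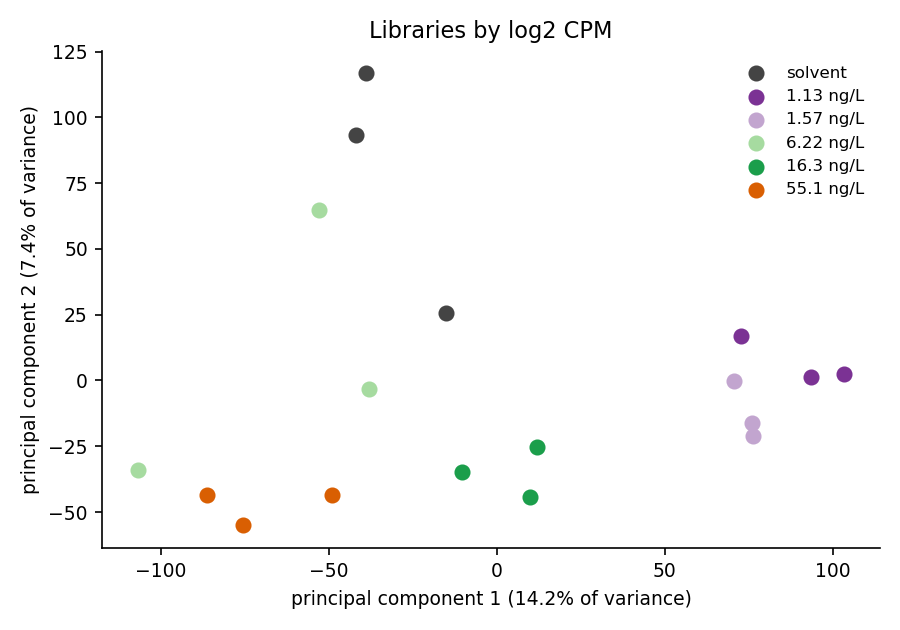
Scores of the 18 libraries on the first (x axis) and second (y axis) principal component of log2 CPM, in arbitrary units, with 14.2% and 7.4% of the variance; each point is a library, coloured by group. The libraries of 1.13 and 1.57 ng/L lie apart from the others on the first component, which does not order the groups by concentration.

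To follow the response to estrogen itself, the genes of egg proteins and of the estrogen receptors were read across all concentrations. In egg-laying vertebrates the liver makes yolk and egg envelope proteins when estrogen binds its receptor. The estrogen receptor gene esr1 rose at every concentration, from 2.83 ± 0.592 CPM in solvent to 6.71 ± 1.22 at 1.13 ng/L, 13.4 ± 1.57 at 1.57 ng/L, 24.3 ± 6.39 at 6.22 ng/L, 35 ± 8.69 at 16.3 ng/L and 37.9 ± 4.27 at 55.1 ng/L (SD, n = 3 libraries each). Its log2 fold changes were 1.23 (adjusted p = 0.0099 in edgeR), 2.24, 3.09, 3.61 and 3.73 (adjusted p = 2.65e-06), each with a standard error of 0.25. Without solvent replicate B the change of esr1 at 1.13 ng/L was 1.08 with an adjusted p of 0.0565. The authors' deposited tables give esr1 as 3 transcripts, none of which passed at 1.13 ng/L (log2 2.12, -6.04 and 1.35 with adjusted p of 0.474, 0.109 and 0.324) or at 1.57 ng/L (0.21, 0.845 and 0.108). In them 1 of the 3, XM_021598364.1, passed at 6.22 (0.026), 16.3 (0.0103) and 55.1 ng/L (0.00179).

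The egg envelope gene zp2.3, of the zona pellucida family, had 2 reads in the solvent group and also rose at every concentration. Its mean level was 1.40 CPM at 1.13 ng/L, 42.6 at 1.57 ng/L, 242 at 6.22 ng/L, 573 at 16.3 ng/L and 687 ± 108 at 55.1 ng/L. The ratio of zp2.3 to solvent was 32.8 at 1.13 ng/L (95% counting interval 8.89 to 274) and 13700 at 55.1 ng/L (3800 to 114000). At 1.13 ng/L zp2.3 had an adjusted p of 0.0123 in edgeR, against 0.0624 without solvent replicate A and 0.0504 without solvent replicate B. The yolk protein gene vtg3, a vitellogenin, also had 2 reads in solvent. It did not pass the threshold at 1.13 ng/L, where its mean was 0.0658 CPM, and rose to 0.97 CPM at 1.57 ng/L, 9.40 at 6.22 ng/L, 24.3 at 16.3 ng/L and 24.4 ± 6.21 at 55.1 ng/L. The ratio of vtg3 to solvent was 21.9 at 1.57 ng/L (5.89 to 184) and 489 at 55.1 ng/L (135 to 4040). Without solvent replicate C its log2 fold changes in edgeR moved from 4.3 to 3.69 at 1.57, 7.55 to 6.95 at 6.22, 8.92 to 8.32 at 16.3 and 8.93 to 8.33 at 55.1 ng/L. At 1.57 ng/L vtg3 had an adjusted p of 0.0114, against 0.0572 without solvent replicate A and 0.0522 without solvent replicate B.

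Several genes that the reference table does not characterise had at most 2 reads over the solvent group and high levels at 55.1 ng/L. XM_021599796.1, with 0 reads in solvent, reached 1410 ± 211 CPM, at least 18600-fold higher than in solvent. XM_021599798.1, also with 0, reached 1050 ± 187 CPM, at least 14000-fold higher, after at least 761-fold at 1.57 ng/L. LOC100135907, with 1 solvent read, reached 1150 ± 252 CPM (ratio 46000, 8250 to 1820000), and LOC100135906, with 2 solvent reads, 514 ± 83.6 CPM (ratio 10200, 2820 to 84100). With so few solvent reads the log2 fold changes in edgeR moved with single solvent libraries: that of LOC100135907 at 55.1 ng/L was 15.33, or 17.56 without replicate C, and that of LOC100135906 was 13.32, or 16.41 without B and 12.72 without C. The other estrogen receptor genes did not pass the threshold at 55.1 ng/L: esr2a changed by -0.45 (SE 0.43, adjusted p = 0.777) and erb2 by 0.22 (SE 0.17, adjusted p = 0.713).

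**Figure D2:**
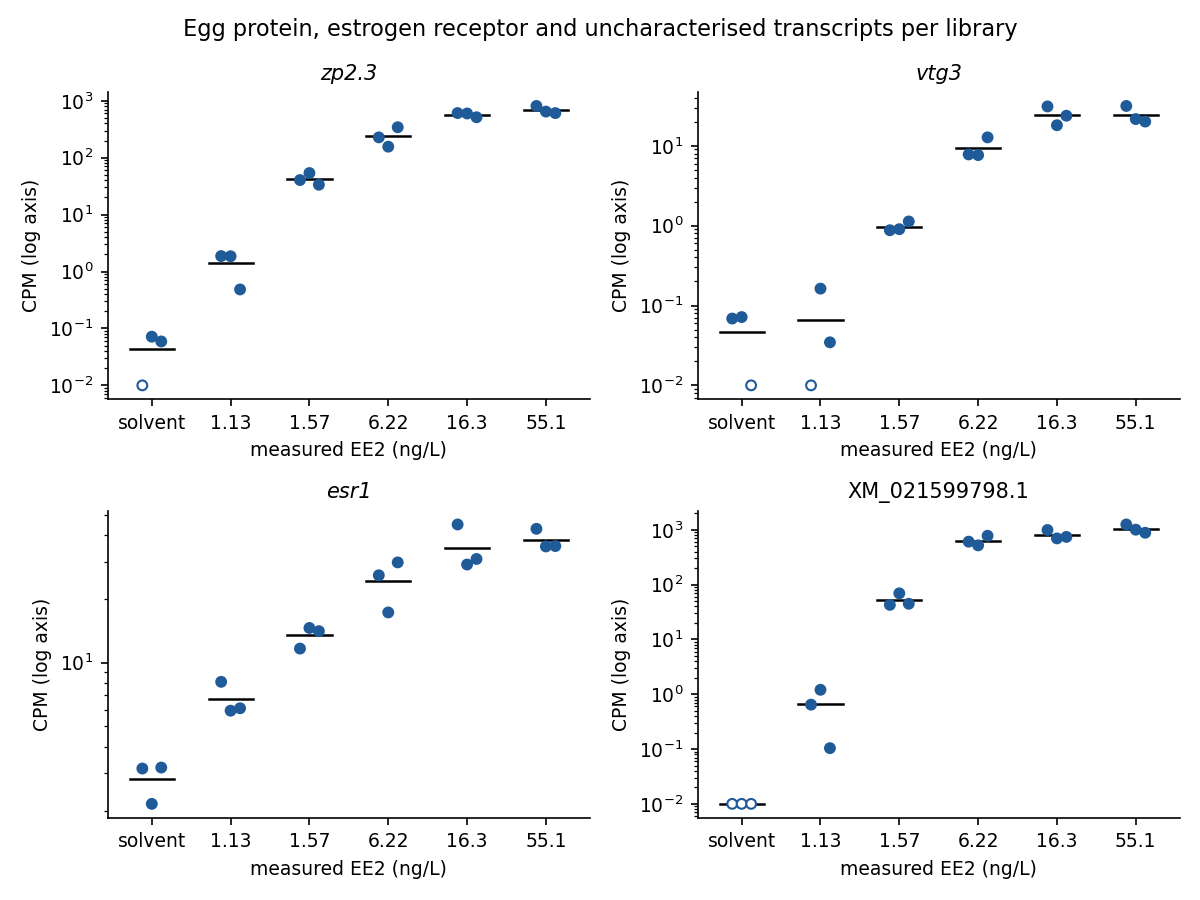
Levels (CPM, log axis) of zp2.3, vtg3, esr1 and XM_021599798.1 in the solvent group and at each EE2 concentration (ng/L, x axis); points are libraries, black bars are group means, and open circles are libraries at 0 reads drawn at 0.01 CPM. Mean zp2.3 runs from 0.0436 CPM in solvent to 687 at 55.1 ng/L, and mean esr1 from 2.83 to 37.9.

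To identify genes that respond to the highest concentration, 55.1 ng/L was compared with solvent. In this comparison 175 genes passed the threshold in edgeR, 107 higher and 68 lower, and 5106 had an unadjusted p under 0.05. Beside the estrogen targets, miox, whose enzyme opens the breakdown of myo-inositol, rose from 9.65 ± 2.43 to 46.1 ± 6.48 CPM (log2 2.25, SE 0.30). The nucleoside phosphorylase gene pnp4b rose from 2.40 ± 0.95 to 13.6 ± 1.45 CPM (log2 2.48, SE 0.32), and the lectin receptor gene cd209 rose from 8.76 to 43.1 CPM (log2 2.29, SE 0.29). The genes mcfd2, for a cargo receptor between the endoplasmic reticulum and the Golgi, cnpy1 of the canopy family and rasd1, for a small GTPase, rose by 1.74, 1.73 and 1.77. The amino acid transporter gene slc6a14 rose by 3.59 (SE 0.66, adjusted p = 0.0298), and this call was lost without solvent replicate A (adjusted p = 0.163), B (0.14) or C (0.0951) and without replicate A of 1.13 ng/L (0.05). Without replicate A of 55.1 ng/L the rise of slc6a14 was 2.16, and its level of 6.16 ± 6.78 CPM shows the spread.

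Among falling genes with a symbol, spp2, for a secreted phosphoprotein of plasma and bone, fell from 28.6 ± 4.58 to 6.99 ± 3.88 CPM, and themis, for a signalling protein of developing T cells, from 13.5 ± 0.721 to 3.67 ± 0.557 CPM. Their log2 fold changes were -2.05 (SE 0.30) and -1.88 (SE 0.21). The lysosomal phospholipase gene pla2g15 fell from 65.3 ± 4.74 to 19.3 ± 2.21 CPM (log2 -1.76, adjusted p = 0.0106), with adjusted p of 0.0575 and 0.0539 without replicates B and C of 55.1 ng/L. Uncharacterised genes with larger falls included XM_021603015.1 (364 to 59.7 CPM) and XR_002472325.1 (141 to 24 CPM), and XM_021616890.1 went from 2.51 CPM to 0 reads. In all, 42 calls were named by the rule or after their values were seen, and 26 of them held without any single library.

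Of the 20 lists, 4 stood higher and 2 lower than other genes at 55.1 ng/L in camera with its preset correlation, and none of the 6 calls held with an estimated one. Egg proteins stood higher (adjusted p = 0.00015, or 0.061 with an estimated correlation): of 6 measured members zp2.3 and vtg3 rose and 4 did not pass (zp3d.1, zranb2, chga and zpr1, the last 3 matched only by symbol shape), with 2 higher and 1 lower when adjusted over the list alone. Genes of protein folding in the endoplasmic reticulum stood higher (0.00389, or 0.272 with an estimated correlation). Of these 22 genes the co-chaperone dnajc3a rose (1.00, adjusted p = 0.0393) and 5 rose when adjusted over the list alone. Skeletal muscle genes stood higher (0.000795, or 0.272 with an estimated correlation), with a rise of the myosin light chain gene mylpfb (0.64, adjusted p = 0.049) among 14 and 6 rises adjusted over the list alone. Leaving out single libraries ended the call of mylpfb in 16 of 18 fits (all but those without replicate B or C of 6.22 ng/L), with adjusted p between 0.0507 and 0.222. It ended that of dnajc3a in 12 fits (all but those without replicate B of 1.13, A or C of 1.57, A of 16.3, and B or C of 55.1 ng/L), with adjusted p between 0.0504 and 0.198. Cholesterol and bile acid synthesis stood higher (0.0494, or 0.291 with an estimated correlation) with 12 of 13 genes above 0, a median of 0.12 and 0 genes past the threshold.

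Cell cycle genes stood lower at 55.1 ng/L (adjusted p = 0.00015, or 0.272 with an estimated correlation), with a median of -0.23, 1 of 13 genes above 0, 0 past the threshold and 4 lower when adjusted over the list alone. Erythrocyte genes stood lower (0.00106, or 0.272 with an estimated correlation), with a median of -0.51, 0 of 7 above 0, 0 past the threshold and 3 lower adjusted over the list alone. Of 17 hepatocyte genes rbp4, the plasma carrier of retinol, rose from 31.9 ± 3.25 to 65.8 ± 7.2 CPM and ahsg2, for the plasma protein fetuin, fell from 60.3 ± 10.1 to 20.3 ± 0.845 CPM, with 1 higher and 2 lower adjusted over the list alone. The call of rbp4 was lost without solvent replicate A (adjusted p = 0.103), B (0.136) or C (0.0532) and without replicate B (0.109) or C (0.0676) of 55.1 ng/L. That of ahsg2 was lost without solvent replicate A (0.0516), B (0.0625) or C (0.0723) and without replicate A (0.0883), B (0.0979) or C (0.0785) of 55.1 ng/L. The total of 175 genes was 87 without solvent replicate A, 90 without solvent replicate B and 103 without replicate B of 55.1 ng/L.

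The comparison of 16.3 ng/L with solvent gave 172 genes in edgeR, 146 higher and 26 lower, with 5671 under an unadjusted p of 0.05. The gene pnp4b rose to 18 ± 4.5 CPM (log2 2.89, SE 0.32), and slc6a14 to 7.92 ± 2.7 CPM (log2 3.95, SE 0.66, adjusted p = 0.0146). The call of slc6a14 was lost without solvent replicate A (adjusted p = 0.114) or B (0.0924) and without replicate B of 16.3 ng/L (0.0528). XM_021599796.1 was at least 28200-fold higher than in solvent. Among the genes that fell, gbrl2 changed by -0.72 (SE 0.11, adjusted p = 0.00773), and its call was lost without solvent replicate B (0.0504) or replicate B of 16.3 ng/L (0.0556). XR_002472387.1 went from 5.22 CPM in solvent to 0 reads.

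Protein folding genes stood higher at 16.3 ng/L (adjusted p = 1.98e-09 in camera, or 0.106 with an estimated correlation), with a median of 0.30 and 20 of 22 genes above 0. Of these dnajc3a rose by 1.42 and LOC100135961, a translocon gene with the synonym sec61ab, by 0.53, and 13 rose when adjusted over the list alone. Egg proteins (0.0051, or 0.117 with an estimated correlation), cholesterol synthesis (0.0388, or 0.415), growth hormone and insulin-like growth factor genes (0.0288, or 0.122) and skeletal muscle genes (0.0288, or 0.468) also stood higher. Past the threshold in these lists were zp2.3, vtg3 and the troponin gene tnni1c (0.58), with 2 egg protein, 0 cholesterol, 3 growth factor and 4 muscle genes higher adjusted over the list alone, beside 1 growth factor gene lower. The total of 172 genes was 97 without solvent replicate A, 102 without solvent replicate B, 301 without solvent replicate C and 108 without replicate B of 16.3 ng/L.

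At 6.22 ng/L, 34 genes passed the threshold in edgeR, 30 higher and 4 lower, with 3610 under an unadjusted p of 0.05. The gene fd6d rose from 28.1 ± 1.02 to 71.7 ± 13.1 CPM (log2 1.35, SE 0.13, adjusted p = 0.000189). The gene miox rose to 42.6 ± 8.31 CPM (log2 2.13, adjusted p = 0.00872), with adjusted p of 0.0854 without solvent replicate A and 0.079 without solvent replicate B. XM_021599798.1 was at least 8480-fold higher than in solvent. The genes that fell were LOC118936301, which went from 5.97 CPM to 0 reads, XM_021600442.1, LOC110500182 and XM_021607821.1. The level of XM_021607821.1 split between groups as the kinds of quantification do, so its fall cannot be told apart from that difference. The call of XM_021600442.1 was lost without solvent replicate A (adjusted p = 0.095) or B (0.0861), any replicate of 6.22 ng/L (0.112, 0.0831 and 0.129) or of 16.3 ng/L (0.0534, 0.058 and 0.0614), and replicate A of 1.13 (0.0642), B of 1.57 (0.0635) or C of 55.1 ng/L (0.0678). That of XM_021607821.1 was lost without solvent replicate A (0.0633) or B (0.0672) and without replicate B (0.052) or C (0.0656) of 6.22 ng/L. Egg proteins stood higher than other genes (adjusted p = 4.08e-07, and 0.0088 with an estimated correlation), with zp2.3 and vtg3 past the threshold and the same 2 adjusted over the list alone.

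Without any gene past the threshold, protein folding (adjusted p = 0.000159, or 0.427 with an estimated correlation), cholesterol synthesis (0.013, or 0.524) and skeletal muscle genes (0.00305, or 0.591) also stood higher at 6.22 ng/L, and erythrocyte genes lower (0.0149, or 0.591). Adjusted over the list alone, 1 protein folding gene, 0 cholesterol genes and 2 muscle genes were higher, and 0 erythrocyte genes lower.

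At the lowest concentrations many more genes differed from solvent. At 1.57 ng/L 2006 genes passed the threshold in edgeR, 1338 higher and 668 lower (66.7% higher), with 9514 under an unadjusted p of 0.05. Expression of zp2.3 was 920 times that in solvent (254 to 7600). The kinase gene styk1b rose by 2.28 (SE 0.35, adjusted p = 0.00546). The gene bsnd, for a chloride channel subunit, fell by 1.53 (SE 0.32, adjusted p = 0.0182), and its call was lost without solvent replicate A (adjusted p = 0.0807) or B (0.0589). With each library's trend with transcript length removed, 2122 genes passed, 1156 higher and 966 lower (54.5% higher). The total was 326 without solvent replicate A, 361 without solvent replicate B, and 661, 501 and 1287 without replicates A, B and C of 1.57 ng/L.

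Cartilage and bone genes stood higher at 1.57 ng/L (adjusted p = 1.12e-07 in camera, and 0.0118 with an estimated correlation) with a median of 1.01 over 10 genes. Of these sparc, bglapl, col9a3, col10a1a and spp1 rose, and 8 rose when adjusted over the list alone. Epidermis genes stood higher (0.00502, or 0.5 with an estimated correlation) with a median of 0.5 over 7 genes: agr2 (0.50) and the tight junction gene cldn1 (1.54) rose, and 5 rose adjusted over the list alone. Outside the called lists igfbp7 (1.78), igfbp5 (0.71) and igf1ra (0.53) rose among 26 growth factor genes, cyp1a3 (1.27) among 21 genes of xenobiotic metabolism and the metallothionein gene mt2 (0.62) among 25 stress genes. The glial gene s100b fell (-0.59), as did the lens gene crygmxl2 (-1.51). The call of crygmxl2 was lost without solvent replicate A (adjusted p = 0.0884) or C (0.0978) and without replicate A (0.118) or B (0.104) of 1.57 ng/L.

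At 1.13 ng/L 3787 genes passed the threshold in edgeR, 2296 higher and 1491 lower (60.6% higher), with 11032 under an unadjusted p of 0.05. With each library's trend with transcript length removed, 3919 genes passed, 2031 higher and 1888 lower (51.8% higher). The lysosomal genes npc1 and npc2, which carry cholesterol out of the lysosome, rose from 46.9 ± 2.51 to 117 ± 3.94 CPM and from 59.9 ± 4.16 to 133 ± 2.49 CPM. Their log2 fold changes were 1.31 (SE 0.09, adjusted p = 7.47e-06) and 1.15 (SE 0.10, adjusted p = 3.2e-05). The ganglioside activator gm2a rose from 21.1 ± 1.9 to 48.5 ± 2.92 CPM, pla2g15 from 65.3 ± 4.74 to 237 ± 21.9 CPM and the lipoprotein gene apoe from 21.9 ± 7.5 to 92.4 ± 4.76 CPM. Their log2 fold changes were 1.2 (SE 0.11), 1.86 (SE 0.27) and 2.07 (SE 0.23). These 5 genes, named after their values were seen, also rose at 1.57 ng/L, by 0.57, 0.65, 0.79, 1.09 and 1.51 in the same order. At 55.1 ng/L npc1 and pla2g15 were lower than in solvent, by -0.50 (SE 0.09, adjusted p = 0.0323) and -1.76. The fall of npc1 was lost without any one library of the solvent, 1.13 or 55.1 ng/L groups, with adjusted p between 0.0508 and 0.175. The kinase gene styk1b rose from 0.882 ± 0.124 to 4.87 ± 1.9 CPM, and the cytochrome P450 gene cyp2k4 fell from 3.85 to 1.68 CPM (log2 -1.19, adjusted p = 0.0119). The call of cyp2k4 was lost without solvent replicate B (adjusted p = 0.0596) or replicate B of 1.13 ng/L (0.0658). XR_002472387.1, with 5.22 CPM in solvent, had 0 reads.

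**Figure D3:**
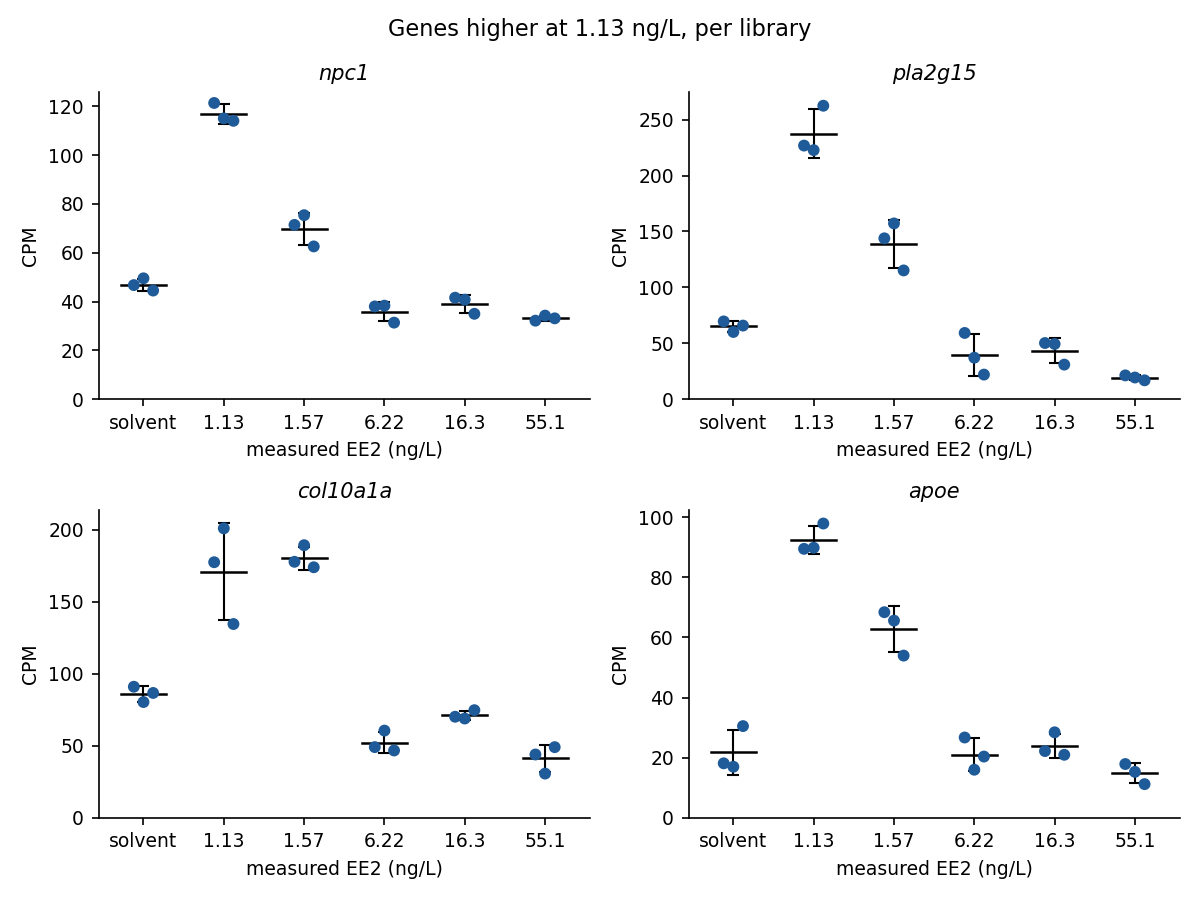
Levels (CPM, linear axis) of genes that rose at 1.13 and 1.57 ng/L, by EE2 concentration (ng/L, x axis); bars are means and error bars SDs of 3 libraries. Mean npc1 is 46.9 CPM in solvent, 117 at 1.13 ng/L and 33.2 at 55.1 ng/L.

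Cartilage and bone genes stood higher than other genes at 1.13 ng/L (adjusted p = 3.5e-08 in camera, and 0.00914 with an estimated correlation), with a median of 1.09 and all 10 genes above 0. Of the 10 genes 7 rose, and 10 rose when adjusted over the list alone. The osteocalcin-like gene bglapl rose from 1.8 ± 0.564 to 5.41 ± 1.14 CPM (log2 1.58, SE 0.31), the osteopontin gene spp1 from 5.91 ± 1.24 to 13.3 ± 1.97 CPM (log2 1.17, SE 0.19) and the collagen X gene col10a1a, a marker of mature cartilage cells, from 86 ± 5.34 to 171 ± 33.7 CPM (log2 0.99, SE 0.16). The collagen IX genes col9a1a (1.09) and col9a3 (1.13), the aggrecan gene acanb (1.08) and sparc (0.71) rose too. Calls of 3 of the 7 depended on single libraries: adjusted p was 0.0562 for acanb without solvent replicate B and 0.0552 without replicate B of 1.13 ng/L, and 0.0526 and 0.0512 for col9a3 without solvent replicates A and B. For sparc it was 0.074 and 0.0732 without solvent replicates A and B and 0.0523 and 0.0672 without replicates A and B of 1.13 ng/L. At 55.1 ng/L col10a1a fell to 41.2 ± 9.47 CPM (log2 -1.06, adjusted p = 0.00838, and 0.0516 without solvent replicate A), the only list member past the threshold there, with 2 lower adjusted over the list alone. The list itself did not differ from other genes at 6.22, 16.3 or 55.1 ng/L (adjusted p = 0.352, 0.642 and 0.132), but stood lower at 55.1 ng/L without replicate A of that group (0.0473).

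**Figure D4:**
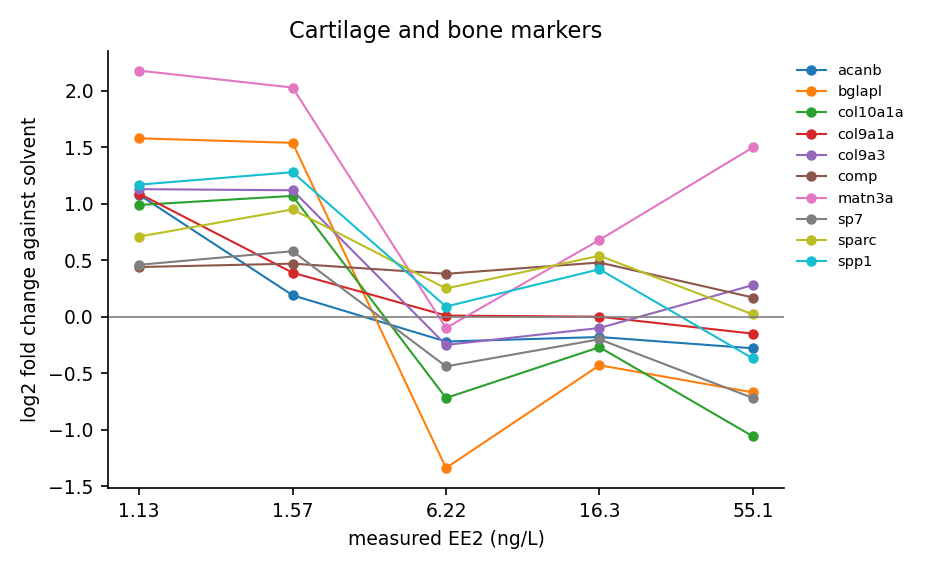
Log2 fold change against solvent (y axis) of the 10 measured cartilage and bone genes at each EE2 concentration (ng/L, x axis); each point is a gene at a concentration, and lines join the values of a gene. All 10 lie above 0 at 1.13 and 1.57 ng/L, and 4 do at 55.1 ng/L.

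Neuron and glia genes stood lower at 1.13 ng/L (adjusted p = 0.00482, or 0.353 with an estimated correlation), with a median of -0.46. Of 8 genes 3 fell (s100b by 0.72, syt12 and syt13, the last 2 matched only by symbol shape), and 5 fell adjusted over the list alone. In the lists that did not differ as a whole, the steroid genes star (-1.19), which brings cholesterol into mitochondria, nr5a1a (-0.58) and hsd17b8 (-0.42) fell among 19 beside the rise of esr1, and pmvk (-0.48) and fdft1 (-0.24) fell among 13 cholesterol genes. Of 26 growth factor genes 5 rose (igfbp7 by 1.69, igfbp5, igf2b, igf1ra and igf2r), although the list's median of -0.15 and mean of -0.05 lie on the other side of 0 from the test's direction (adjusted p = 0.613). Also higher were apoe, apoba (0.92) and tfa (0.88) of 17 hepatocyte genes, mt2 (0.80) and gpx4a (1.04) of 25 stress genes and mcm7 (0.49) and top2a (0.36) of 13 cell cycle genes. The chromogranin gene chga, matched to the egg proteins only by symbol shape, fell (-0.59, adjusted p = 0.0104). Each of the other lists had at most 2 members past the threshold. The total of 3787 genes was 1437 without solvent replicate A, 1528 without solvent replicate B, and 1867 and 1350 without replicates A and B of 1.13 ng/L.

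Of the 46999 genes, 29.8% at 1.13 ng/L, 26.2% at 1.57 ng/L, 11.3% at 6.22 ng/L, 16.3% at 16.3 ng/L and 15.5% at 55.1 ng/L had no overlap between exposed and solvent libraries, where chance gives 10%. Since solvent and 55.1 ng/L were quantified in one way and the other groups in another, the low concentrations were also compared within the second set. Against 16.3 ng/L, 2023 genes differed at 1.13 ng/L and 355 at 1.57 ng/L, and 7605 differed between 1.13 and 6.22 ng/L. Leaving out single libraries gave 733 to 2211, 106 to 395 and 3811 to 7530 genes in the same order. Between 1.13 and 1.57 ng/L 21 genes differed. The authors' deposited tables, read at the same threshold, list 4986 transcripts at 1.13 ng/L, 3762 at 1.57 ng/L, 376 at 6.22 ng/L, 1036 at 16.3 ng/L and 875 at 55.1 ng/L.

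**Figure D5:**
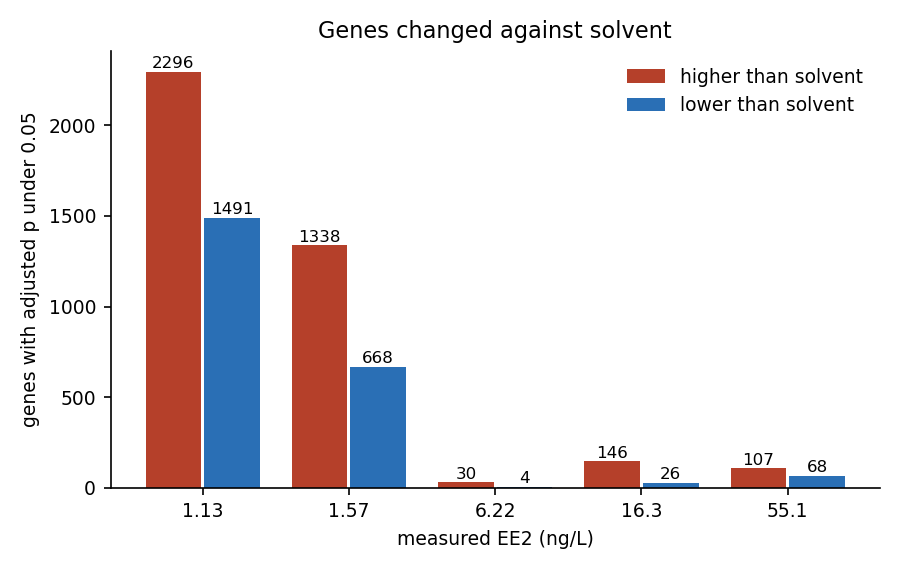
Number of genes past the threshold (y axis) against solvent at each EE2 concentration (ng/L, x axis); bars give genes higher and lower than in solvent. The counts are 3787 at 1.13 ng/L, 2006 at 1.57 ng/L, 34 at 6.22 ng/L, 172 at 16.3 ng/L and 175 at 55.1 ng/L.

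To see whether the response still grew at the upper end, 55.1 was compared with 16.3 ng/L. In this comparison 21 genes passed the threshold in edgeR, 8 higher and 13 lower, with 5348 under an unadjusted p of 0.05. The estrogen targets did not pass: zp2.3 changed by 0.26 (SE 0.30, adjusted p = 0.812), vtg3 by 0.01 (SE 0.28, adjusted p = 1) and esr1 by 0.12 (SE 0.20, adjusted p = 0.895). XM_021593077.1 fell from 11.6 to 3.4 CPM (log2 -1.77, SE 0.22), XM_021616890.1 went from 3.24 CPM to 0 reads, and XR_002472387.1 went from 0 reads to 5.45 CPM, near its solvent level. The level of XR_002472387.1 split between groups as library totals do, so its rise cannot be told apart from that difference. The retinal phosphodiesterase gene pde6gb fell from 21.0 to 14.3 CPM (log2 -0.55, SE 0.07, adjusted p = 0.0118), with adjusted p of 0.0615 without replicate B of 16.3 ng/L and 0.0504 without replicate C of 55.1 ng/L. These groups were quantified in different ways, and of 13 named calls 3 held without any single library. The total was 13 without replicate A of 1.13 ng/L, 12 without replicate A and 12 without replicate B of 1.57 ng/L, 11 and 43 without replicates A and C of 6.22 ng/L, 7 and 12 without replicates B and C of 16.3 ng/L, and 8 without replicate C of 55.1 ng/L. A fit to the 6 libraries alone gave 0 genes in edgeR, with 4010 under an unadjusted p of 0.05 and 535 genes in DESeq2 on all libraries.

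To identify genes whose expression follows the concentration, a trend was fitted across all groups, and 558 genes passed the threshold in edgeR, 335 rising and 223 falling, with 7561 under an unadjusted p of 0.05. Slopes per unit of log2 concentration were 1.63 (SE 0.29, adjusted p = 0.00922) for zp2.3, 1.41 (SE 0.19) for vtg3, 0.84 (SE 0.12) for slc6a14 and 0.59 (SE 0.07) for esr1. Smaller slopes with smaller errors belonged to cd209 (0.46, SE 0.05), cnpy1 (0.36, SE 0.03) and mcfd2 (0.36, SE 0.04). The largest slope was that of XM_021591842.1 (2.28, SE 0.16). Of the falling genes, themis had a slope of -0.36 (SE 0.04), pla2g15 of -0.55 (SE 0.11, adjusted p = 0.0213) and leg1, a gene of liver development, of -0.49 (SE 0.10, adjusted p = 0.0225). On linear concentration the trend calls of zp2.3, vtg3, slc6a14, esr1, pla2g15 and leg1 were lost. Without the 1.13 and 1.57 ng/L groups those of zp2.3, vtg3, slc6a14, pla2g15 and leg1 were lost, with slopes of 1.58, 0.97, 0.72, -0.26 and -0.25, and without the 55.1 ng/L group those of pla2g15 (-0.50) and leg1 (-0.51). The calls of pla2g15 and leg1 were also lost without replicate A (adjusted p = 0.0599 and 0.0674), B (0.0679 and 0.0545) or C (0.0611 and 0.0531) of 55.1 ng/L. Within the 4 groups of one quantification 1188 genes had a trend, 374 rising and 814 falling, and without the 1.13 and 1.57 ng/L groups 43 did, 35 rising and 8 falling.

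Of the 20 lists, 6 stood higher and 3 lower in slope than other genes in camera, and none of these 9 calls held with an estimated correlation, where adjusted p lay between 0.235 and 0.347. Slopes stood higher than those of other genes for skeletal muscle (adjusted p = 7.3e-05, 4 of 14 genes past the threshold: myl1, mylpfb, tnni1c and ckmb), egg proteins (0.00335, 2 of 6: zp2.3 and vtg3), protein folding (0.00309, 3 of 22: calr3a, creld2 and dnajc3a), cholesterol synthesis (0.00309, 0 of 13), steroid genes (0.0251, 1 of 19: esr1) and neuron and glia genes (0.0225, 0 of 8). They stood lower for cell cycle genes (0.000787, 0 of 13), cartilage and bone (0.00309, 2 of 10: col10a1a and sp7) and erythrocyte genes (0.0225, 0 of 7). A slope does not mean a steady course. From 1.13 to 55.1 ng/L the medians against solvent were 1.09, 1.01, -0.16, -0.05 and -0.21 for cartilage and bone genes and -0.46, -0.10, 0.05, 0.02 and 0.08 for neuron and glia genes, which lay farthest from solvent at the lowest concentrations. Adjusted over the list alone, 7 muscle, 2 egg protein, 4 protein folding, 1 cholesterol, 2 steroid and 1 neuron gene rose. On the other side 2 cell cycle, 6 cartilage and bone, 3 erythrocyte, 1 egg protein and 1 steroid gene fell. The total of 558 genes was 1131 without solvent replicate C, 329 and 358 without replicates A and B of 1.13 ng/L, 321 without replicate C of 16.3 ng/L, and 266, 244 and 307 without replicates A, B and C of 55.1 ng/L.

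Over the 6 comparisons 29 of 120 list tests passed the threshold, and 3 held with an estimated correlation: cartilage and bone at 1.13 and 1.57 ng/L and egg proteins at 6.22 ng/L. Median, mean and test had one sign in all 29 and differed in sign in 23 of the other 91. The list members past the threshold (42, 23, 3, 6 and 8 from 1.13 to 55.1 ng/L) all had their 3 exposed libraries on that side of the solvent mean. Passing on the same libraries makes this likely, so it adds no support. The other 9 lists did not pass in any comparison with the members, libraries and filter as reported. Their adjusted p lay between 0.257 and 0.779 for xenobiotic metabolism, 0.249 and 0.851 for the thyroid axis, 0.157 and 0.956 for pituitary and hypothalamic hormones, and 0.249 and 0.959 for immune genes. It lay between 0.0529 and 0.544 for heat shock, metallothionein and glucocorticoid response genes, 0.233 and 0.885 for hepatocyte, 0.428 and 0.905 for exocrine pancreas, 0.343 and 0.676 for eye, and 0.0909 and 0.949 for germ cell genes. The 7 measured members of the exocrine pancreas list matched only by symbol shape, so that list says nothing of the tissue.

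Without the members matched only by symbol shape, a choice made after seeing the data, 34 list tests passed instead of 29. Cholesterol synthesis at 55.1 ng/L no longer did (adjusted p = 0.098). The heat shock, metallothionein and glucocorticoid response genes then stood higher at 1.57 (0.0396), 16.3 (0.0238) and 55.1 ng/L (0.0175). So did egg proteins (0.000479) and protein folding genes (0.0244) at 1.57 ng/L and epidermis genes at 1.13 ng/L (0.045). The heat shock list also passed with the length trend removed at 1.57 ng/L (0.0324) and with the strict filter at 16.3 ng/L (0.0379). Leaving out single libraries brought it past the threshold at 1.57 ng/L (0.036 without solvent replicate C, 0.0369 without replicate A of 1.57 and 0.046 without B of 55.1 ng/L) and at 16.3 ng/L (0.0408 without solvent replicate C, 0.0339 without replicate A of 1.57 and 0.0489 without A of 16.3 ng/L). It did so for hepatocyte genes at 1.57 ng/L (0.0497 without solvent replicate C) and 6.22 ng/L (0.0336 without solvent replicate C, 0.0174 without replicate B of 6.22 ng/L). Immune genes passed at 1.57 ng/L (0.0392 without solvent replicate C, 0.0307 without replicate B of 1.57 ng/L), and germ cell genes stood lower in slope without replicate C of 55.1 ng/L (0.0419). Among lists called elsewhere, growth factor genes stood higher in slope without any replicate of 1.13 ng/L, A or C of 1.57, A or B of 6.22, or C of 55.1 ng/L (8 fits, adjusted p between 0.035 and 0.0488). Without solvent replicate C, epidermis genes passed at 1.13 (0.0366) and 16.3 ng/L (0.0408), steroid genes at 16.3 ng/L (0.0411) and protein folding genes at 1.57 ng/L (0.036). Epidermis genes also passed at 16.3 ng/L without replicate A of that group (0.0327), and protein folding genes at 1.57 ng/L without replicate A of that group (0.0369) or with the length trend removed (0.0412).

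Of the 29 list calls, 18 held without any single library. Cholesterol synthesis depended most on single libraries. Its call at 6.22 ng/L was lost without solvent replicate A (adjusted p = 0.265) or C (0.111) and without replicate B (0.188) or C (0.159) of 6.22 ng/L. At 55.1 ng/L it was lost without solvent replicate A (0.184) or C (0.0885), any replicate of 6.22 ng/L (0.0505, 0.0564 and 0.0553) and replicate A (0.0846) or C (0.224) of 55.1 ng/L. At 16.3 ng/L it held only without solvent replicate B and replicates A or C of 1.57 ng/L, with adjusted p of 0.0579 to 0.201 otherwise. Skeletal muscle was lost at 6.22 ng/L without replicate C of that group (0.113), and at 16.3 ng/L without solvent replicate A (0.0837) or B (0.0863) and without replicate B (0.186) or C (0.0593) of 16.3 ng/L. Growth factor genes at 16.3 ng/L were lost without solvent replicate A (0.0823) or replicate B of 16.3 ng/L (0.0983), and protein folding at 55.1 ng/L without replicate A of that group (0.0645). Erythrocyte genes at 6.22 ng/L were lost without solvent replicate A (0.0828) or C (0.148) or replicate A (0.0907) or B (0.056) of 6.22 ng/L. Their trend was lost without solvent replicate A (0.054) or C (0.0649) or replicate B (0.182) or C (0.0533) of 55.1 ng/L. The trend of steroid genes was lost without solvent replicate B (0.0709), and that of neuron and glia genes without any replicate of 6.22 ng/L (0.0571, 0.062 and 0.0665) or of 55.1 ng/L (0.0658, 0.11 and 0.109).

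To express the response as a concentration, a benchmark was computed for each of the 558 genes with a trend. Its median was 3.54 ng/L (jackknife SE 1.75) and its 10th percentile 0.91 ng/L (SE 0.55). The 20th lowest value was 0.44 ng/L (SE 0.58), and 0.05 ng/L without solvent replicate C. The median was 2.88 ng/L for the 335 rising and 3.84 ng/L for the 223 falling genes. Each curve only rises or only falls, so it cannot follow a gene that rose at low and fell at high concentrations. LOC110523893, with log2 fold changes of 2.94 at 1.13 and -2.46 at 55.1 ng/L, counts as falling with a benchmark of 3.663 ng/L. For such a gene the benchmark does not mark where expression first left the solvent level. Among the estrogen targets the benchmark was 0.326 ng/L for esr1, 0.669 for zp2.3, 0.803 for XM_021599798.1 and 1.029 for vtg3. For 75 genes (13.4%), all of these targets included, the benchmark lay under the lowest tested concentration of 1.13 ng/L and so rests on the shape of the curve. At 1.13 ng/L itself vtg3 did not pass the threshold against solvent. The median was 21.9 ng/L with the linear curve alone and 1.05 ng/L without the 1.13 and 1.57 ng/L groups, where 43 genes had a trend. The lower values depended on the settings too: the 10th percentile and the 20th lowest value were 1.52 and 0.89 ng/L at a departure of 1.5 residual SDs, and 15.79 and 13.32 ng/L with the linear curve alone. With only the 194 genes whose groups differed by at least 1 log2 unit both were 0.8 ng/L. Without the 1.13 and 1.57 ng/L groups they were 0.07 and 0.97 ng/L. These values and the median of 1.05 ng/L lie under 6.22 ng/L, the lowest concentration left, and so rest on the shape of the curve. The 20th lowest of 43 genes lies near their median and cannot be compared with that of 558. The set of genes behind the median of 3.54 ng/L thus depends on the 1.13 and 1.57 ng/L groups, whose difference from solvent may come from a batch.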

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

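Chosen only after the result was seen were the tests on the kind of quantification, on fragment length, on the stage of development, on thinned libraries and on the length trend, and all tests of 1.57 ng/L on the number of genes, those against 55.1 ng/L last, once the ones against 16.3 ng/L had left 2 explanations undecided.

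For 24 genes the effects at 1.13 and 55.1 ng/L went in opposite directions, each past the threshold against solvent, and all 24 were higher at 1.13 and lower at 55.1 ng/L. These genes were picked as past the threshold also in edgeR for 1.13 against 55.1 ng/L. The adjusted p of the difference is therefore no separate support. Of the 24 genes 10 are named. The effect of npc1 at 1.13 ng/L exceeded that at 55.1 ng/L by 1.81 log2 units (1.31 and -0.50, adjusted p = 9.15e-08 for the difference), that of pla2g15 by 3.62 (1.86 and -1.76, 5.4e-06), that of col10a1a by 2.05 (0.99 and -1.06, 5.43e-06) and that of leg1 by 3.21 (1.60 and -1.60, 2.45e-05). The other genes have no symbol. Their differences were 5.41 for LOC110490263 (adjusted p = 4.62e-07), 5.40 for LOC110523893 (2.92e-06), 5.17 for XM_021603008.1 (1.09e-05), 5.15 for LOC110526546 (1.73e-05), 4.12 for XM_021603015.1 (2.76e-05) and 3.74 for XR_002472325.1 (1.54e-05). At 55.1 ng/L the call of LOC110526546 was lost in 15 of 18 fits without a single library (all but those without replicate A or C of 6.22 or C of 55.1 ng/L, adjusted p up to 0.123). That of npc1 was lost in 9 (up to 0.175), of leg1 in 7 (any replicate of solvent or 55.1 ng/L or A of 1.13 ng/L, up to 0.115), of XM_021603008.1 in 5 (solvent A or C or any of 55.1 ng/L, up to 0.11), of pla2g15 in 2 and of col10a1a in 1. The 1.13 and 55.1 ng/L groups were quantified in different ways, so a part of any difference may come from that, although 1.0 times as many genes differed from solvent at 16.3 ng/L, quantified as 1.13 ng/L was, as at 55.1 ng/L.

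Many more genes differed from solvent at 1.13 and 1.57 ng/L than at 55.1 ng/L. Depth, transcript length and the quantification could each give such a pattern, but the counts at 1.13 and 1.57 ng/L were 20.2 and 10.6 times that at 55.1 ng/L with all libraries thinned to the lowest total and 19.5 and 10.6 times with the length trend removed, while 16.3 ng/L, quantified as they were, gave 1.0 times the count of 55.1 ng/L, which argues against each as the whole cause. Fragment length, read as the library median of length minus effective length, was 179 to 195 bases in solvent, 231 to 241 at 16.3 ng/L and 242 to 256 at 1.13 ng/L. On all libraries in edgeR, 1.13 against 16.3 ng/L gave 11.8 times the count of 16.3 ng/L and 11.6 times that of 55.1 ng/L against solvent. In that fit this argues against fragment length and the solvent libraries as the whole cause at 1.13 ng/L. Both margins were smaller without replicate B of 1.13 ng/L (733 genes against 158 and 147), without replicate C of 16.3 ng/L (751 against 128 and 160) and in DESeq2 (4488 against 1011 and 816). Held to every such fit, as the test at 1.57 ng/L was, both explanations stay undecided at 1.13 ng/L. For 1.57 ng/L (244 to 252 bases) the 355 genes against 16.3 ng/L were only 2.1 and 2.0 times the counts of 16.3 and 55.1 ng/L against solvent. But 1.57 against 55.1 ng/L (172 to 193 bases), without solvent libraries, gave 4684 genes. That is 223.0 times the 21 of 55.1 against 16.3 ng/L, which spans the same kinds of quantification and nearly the same lengths (103.7 to 643.6 times without single libraries, 6960 against 535 genes in DESeq2). It is 26.8 times the count of 55.1 ng/L against solvent (17.8 to 49.7, and 8.5 in DESeq2), so by adjusted counts both are argued against as the whole cause at 1.57 ng/L. Under an unadjusted p of 0.05 in edgeR the margins were far smaller. There 11569 genes differed between 1.57 and 55.1, 8464 between 1.13 and 16.3 and 5556 between 1.57 and 16.3 ng/L. Beside these stood 5671 for 16.3 against solvent, 5348 for 55.1 against 16.3 ng/L and 5106 for 55.1 against solvent. The size of each ratio thus depends on the cutoff. Each technical cause was tested alone and as the whole cause, so a part from them together stays open. The 1.13, 1.57 and 16.3 ng/L groups had library totals of 19679734 to 32851570, against 12658946 to 17076432 in the other groups. Their fragment lengths were 231 to 256 bases, against 172 to 216. Against 16.3 ng/L, 2023 genes differed at 1.13 and 355 at 1.57 ng/L, where 3787 and 2006 differed from solvent. Also open are a response that is strong only at low concentrations and an unrecorded batch shared by the 1.13 and 1.57 ng/L groups. The response and the batch cannot be told apart because any such batch coincides with the groups.

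Cartilage and bone genes stood higher at 1.13 ng/L. A trend with transcript length as the cause is argued against by the adjusted p of 1.72e-08 with that trend removed. A later stage of development at sampling could raise these genes, and then other differentiated tissues might be higher too. The median of 5 other tissue lists' medians was -0.12, with single values of 0.12 for hepatocyte, -0.14 for erythrocyte, -0.12 for muscle, -0.07 for eye and -0.46 for neuron and glia genes and an SD of 0.21. Epidermis genes, not among these 5 lists, had a median of 0.47 at 1.13 ng/L. At 1.57 ng/L, where cartilage and bone genes also stood higher, the 5 medians were 0.14, 0.10, 0.11, -0.05 and -0.10 in the same order. Since the median of -0.12 is within the spread of the lists from 0, a stage difference and an effect of EE2 on the skeleton both stay open, as does the batch.

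The 3 libraries of a concentration and the 3 of solvent can be split in 10 ways, which cannot give a share under 0.1. In each comparison the count was reached by 1 split, the real one: 3787 genes at 1.13 ng/L (highest of the other splits 2), 2006 at 1.57 ng/L (3), 34 at 6.22 ng/L (3), 172 at 16.3 ng/L (3), 175 at 55.1 ng/L (4) and 21 between 16.3 and 55.1 ng/L (2). For the trend, 1 of 100 random orders of the libraries, the real one, gave as many genes (558, highest other 3). Such orders break up the groups, so this shows that the groups differ. It cannot tell a trend with EE2 from any other difference between groups, such as a batch. For the lists, 2 of 100, the real one included, gave at least 29 calls (highest other 35), a share under 0.05. So many calls are thus rare in such orders, but 1 order gave more than the real one, so chance is not excluded. The other 99 orders had a median of 10 list calls (quartiles 6 and 13.5), so a part of the 29 is expected by chance, and which ones is not known.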

How the results depend on the processing

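Chosen after seeing the data were the thinned libraries, the removal of the length trend, the trend within 4 groups, the trend and benchmark without the 1.13 and 1.57 ng/L groups, and the lists without members matched by symbol shape. For each value that changed below, the cause was not tested unless fewer libraries or genes explain it.

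Counts of genes stayed within 1.5 times the reported ones, in every comparison, with DESeq2 size factors, without a filter, with the strict filter and with the length trend removed. DESeq2's Wald test gave more genes everywhere: 6414 at 1.13, 4658 at 1.57, 328 at 6.22, 1011 at 16.3 and 816 at 55.1 ng/L, 535 between 16.3 and 55.1 ng/L (241 higher, 294 lower) and 2367 with a trend. A fit to only the 6 libraries of a comparison, which has fewer degrees of freedom, gave 1624, 487, 15, 93 and 59 genes from 1.13 to 55.1 ng/L, and 0 between 16.3 and 55.1 ng/L (4010 under an unadjusted p of 0.05 in edgeR). With transcripts as listed there were 2247 at 1.13 ng/L, 999 at 1.57 ng/L and 307 with a trend. Asking for a change of at least 2-fold left 930 at 1.13, 514 at 1.57, 96 at 16.3 and 95 at 55.1 ng/L and 10 between 16.3 and 55.1 ng/L. Thinning to the lowest total moved only the count between 16.3 and 55.1 ng/L past 1.5 times, to 13.

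A block for the replicate letter gave 11 genes between 16.3 and 55.1 ng/L and 349 with a trend. The letters do not pair the libraries: of 45 same-letter pairs across groups 6 correlated above 0.1 (median 0.024), and 6 of 18 libraries correlated best with their own letter. The trend gave 71 genes on linear concentration, 141 without the 55.1 ng/L group, 1188 within the 4 groups of one quantification (374 rising, 814 falling) and 43 without the 1.13 and 1.57 ng/L groups (35 rising, 8 falling). Of the 29 list calls 3 remained with an estimated correlation, and 34 tests passed without members matched by symbol shape. The benchmark median moved to 21.9 ng/L with the linear curve alone (10th percentile 15.79) and to 1.05 ng/L without the 1.13 and 1.57 ng/L groups (0.07). The values without those groups lie under the lowest concentration left, 6.22 ng/L, and rest on the shape of the curve.

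Leaving out each library in turn gave 1350 to 3892 genes at 1.13, 326 to 2481 at 1.57, 27 to 44 at 6.22, 97 to 301 at 16.3 and 87 to 188 at 55.1 ng/L, 7 to 43 between 16.3 and 55.1 ng/L and 244 to 1131 with a trend. It gave 22 to 33 list calls and benchmark medians of 2.42 to 4.34 ng/L. A group with a library left out keeps 2, whose spread is pooled with the other groups.

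Of the named genes' values, 1283 kept direction and side of the threshold and 183 lost the call under the other alternatives; with 1 library left out these were 2527 and 473, while 2 gained a call and 4 changed sign. The sign changes concern values not past the threshold. At 1.13 ng/L vtg3 ran from -1.11 (without replicate B of 1.13 ng/L) to 1.08, with -0.06 without solvent replicate C. At 55.1 ng/L zp3d.1 ran from -0.08 (without replicate A of 55.1 ng/L) to 0.30, and zpr1 from -0.11 to 0.09 (without the same replicate). For 9 values DESeq2 gave no adjusted p. Trend calls of zp2.3, vtg3 and slc6a14 were lost without the 1.13 and 1.57 ng/L groups, with slopes of 1.58, 0.97 and 0.72. Depth limits what can be read of genes near 0 reads in solvent, whose fold changes are bounds or wide ratios. In simulated counts 39% to 49% of 2-fold changes were found, so smaller changes were often not detectable.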

Other observations

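Chosen only after the result was seen were all tests in this part.

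The rise of npc1, npc2, gm2a and pla2g15 at 1.13 ng/L raised the question whether lysosomal genes rose as a class, for which a list of 30 genes was written. At 1.13 ng/L 12 rose and 1 fell (18 and 3 adjusted over the list alone), with a median of 0.40 and 23 of 30 above 0. Beside the genes that raised the question, the genes that rose included the cathepsin genes ctsc (0.99), ctsz (0.80), ctsa (0.64) and ctsla (0.54), cathy (1.18, also matched by the immune list), fuca2 (0.44) and lamp2 (0.35), and the proton pump gene atp6v0ca fell (-0.36). A candidate explanation is a shared rise of lysosomal genes: without npc1, npc2, gm2a and pla2g15, the other 26 genes stood higher than other genes in camera (p = 0.000206, or 0.0101 with an estimated correlation), with a median of 0.36 and 19 of 26 above 0. At 1.57 ng/L 8 rose and 1 fell (median 0.29), and at 55.1 ng/L 1 rose (npc2) and 2 fell. This remains a hypothesis, since the list was chosen on these data and a batch shared by the low concentrations cannot be told apart from them.

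A list of 125 genes of ribosomal proteins and the mitochondrial respiratory chain moved the other way. At 1.13 ng/L 0 rose and 20 fell in edgeR (37 fell adjusted over the list alone), with a median of -0.24, or -0.17 with the length trend removed. In camera the list stood lower (p = 9.3e-15, or 0.0913 with an estimated correlation). At 1.57 ng/L 6 fell. The list stood higher at 6.22 ng/L (median 0.18, p = 6.61e-11, or 0.148 with an estimated correlation), 16.3 ng/L (median 0.07, p = 0.00276, or 0.492) and 55.1 ng/L (median 0.13, p = 2.53e-06, or 0.287), with no gene past the threshold in edgeR at any of them. With the length trend removed these medians were smaller, at 0.09, 0.05 and 0.09.

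The single transcripts XM_021607820.1 and XM_021607821.1 changed places between groups. XM_021607820.1 had 88.1 CPM in solvent and 102 at 55.1 ng/L, against 369, 389, 448 and 407 CPM from 1.13 to 16.3 ng/L, and XM_021607821.1 had 632 and 645 CPM against 260, 237, 259 and 245. Their sum was 720 ± 42 CPM in solvent and 747 ± 52 at 55.1 ng/L, and 629 ± 12, 625 ± 24, 708 ± 33 and 652 ± 25 in the others. The groups split as the kinds of quantification do. The mean of fus was 35.5 CPM in solvent, 41.6 at 6.22 ng/L and 38.9 at 55.1 ng/L, and 80.6, 82.0 and 93.1 CPM at 1.13, 1.57 and 16.3 ng/L. XR_002472387.1, at 5.22 CPM in solvent, 6.01 at 6.22 ng/L and 5.45 at 55.1 ng/L, had 0 reads in the same 3 groups. Those groups had the highest library totals and the longest fragments. The changes of fus and XR_002472387.1 cannot be told apart from these differences between libraries.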
